A study of Homo sapiens with 18 samples.

How the data were processed

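The series held 18 libraries of T47D-MTVL cells, a human breast cancer line that carries a hormone-inducible luciferase reporter. Per the labels, all cells were moved to serum-free medium, without a stated length of time for RNA-seq. Those for Hi-C and ChIP-seq spent 1 day in it and were then given 0 or 10 nM R5020, a synthetic progestin, and fixed with 1% formaldehyde for 10 min. Hi-C was made at 0 and 60 min with each of the restriction enzymes HindIII and NcoI, 1 library per enzyme and time. RNA-seq was made from untreated cells, after 60 and 360 min of progestin and after 360 min of oestradiol, 1 library each. The labels name the hormone of these RNA libraries as progesterone and give no dose. ChIP-seq of H3K36me2, H3K14ac, H3K27me3 and the linker histone H1.2 was made at 0 and 30 min, and of CTCF at 0 and 60 min, 1 library each. Per the labels, the H3K27me3 antibodies of the 2 times had different catalogue numbers from 1 supplier. The submitters' processing notes name Bowtie 1.0.0, HOMER and BWA and the builds GRCh37 and hg19, without saying which tool made which file.

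The deposited RNA table held expected counts, that is read counts per Ensembl gene that the authors had not normalised, with fractional values for some genes. Of 49307 genes, 42357 had whole counts in all 4 libraries, where whole means no decimal part as deposited. In each library 99.9% of the whole values were even, so a read pair was taken as 2 reads. Reads with a fractional share were used as deposited for ratios and rounded where a tool or an interval needed whole numbers. The ChIP-seq table of deposited counts gave whole reads per 100 kb bin for 30376 bins on 23 chromosomes, without normalisation by the authors. The deposited Hi-C matrices held counts of contacts between 30386 bins of 100 kb, symmetric and whole, with each contact on the diagonal entered 2 times, which was undone. How the authors handled duplicate or multiply mapping reads is not stated. Per the file headers, the CTCF peaks were called with HOMER findPeaks against an input library at a false discovery rate of 0.001 and 4-fold over input and over the local region. Per the file headers, these lists give a signal (tags per peak, scaled to the library), a ratio to input and a peak score.

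Gene symbols came from a GRCh38 annotation (release GCF_000001405.40 of the reference), matched by identifier for 93.4% of the table. That annotation was used only for symbols and for the order and overlap of genes along chromosomes, and none of its coordinates is printed. All positions given are those of the files (hg19). Because no gene coordinates on hg19 were used, the planned grouping of RNA ratios by Hi-C domain was not run. The correlation between neighbouring genes (log2 ratios limited to 3 either way) was computed in its place, as an alternative chosen after the data were seen.

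Samples were grouped by assay, target, hormone and time. The groups, the comparisons, the rules, the gene lists and most alternatives were chosen before the data were examined. RNA ratios were log2 ratios of CPM (reads scaled by the total of the library), with 0.5 CPM added to each side. A gene passed the 2-fold rule when this ratio was at least 2-fold, the libraries together held at least 50 reads, and the exact binomial (Clopper-Pearson) 95% interval of the ratio, computed on read pairs, excluded no change. Folds are given without the added 0.5 CPM, and a fold against a library with 0 reads is a lower bound against a floor of 3 read pairs. ChIP-seq bins were compared in the same way, scaled by total reads, with at least 100 reads and 1.5-fold. With 1 library per condition there was no test of these differences. Intervals and floors cover counting error only, and read pairs without molecular identifiers are not independent molecules.

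Named genes were the 10 highest and the 10 lowest ratios per comparison among genes with at least 100 reads, at least 5 CPM in the higher library and an interval that excluded no change, plus the 2 highest and 2 lowest members of each list and the receptor genes PGR and ESR1. Nearly all genes so ranked had fractional counts, so a second ranking of genes with whole counts only was added after the data were seen. Named bins were the 3 highest and 3 lowest per mark with at least 300 reads, the 3 strongest CTCF peaks seen at 1 time, and the 5 Hi-C bins or domains with the largest mean change of 1 sign in both enzymes.

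The 15 gene lists were progestin and glucocorticoid receptor targets, oestrogen receptor targets, immediate early genes, G1/S and DNA replication, G2/M and mitosis, ribosome biogenesis, interferon response, sterol and fatty acid synthesis, metallothioneins, glycolysis, luminal epithelium, markers of basal, mesenchymal, blood and vessel cells, architectural proteins and linker histones, polycomb and SWI/SNF, and housekeeping genes. Each list's median was set against 10000 random lists of the same size matched on mean expression. Over 60 such medians, about 3 would lie outside a 95% range by chance, so percentiles are given without adjustment, and random lists leave out the correlation between genes of 1 list.

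Hi-C bins below 20% of the median coverage were left out, which kept 27761 bins. The insulation score was the log2 mean contact across a bin in a square of 500 kb, over the chromosome mean, so that a higher score means more contacts across the bin. The compartment score was the first eigenvector of the correlation matrix of observed over expected contacts, scaled to unit SD and oriented by the ratio of H3K36me2 to H1.2 reads. Borders were insulation minima at least 0.15 deep and lowest within 3 bins, averaged over all 4 libraries, and domains spanned 3 to 40 bins. The coverage limit, border depth and domain sizes were set after the files were opened. Libraries at 60 and 0 min were compared with limma, with the enzyme as a block and Benjamini-Hochberg adjusted p at 0.05. The enzyme was the replicate, and the labels do not say that the enzymes stand for separate cultures. These p-values therefore measure only the spread between these libraries, pooled over bins or domains by limma. For single values such as the cis share, an exact two-sided test that exchanges the times within each of 2 enzymes cannot go below 0.5, so each library's value is given. Uncorrected compartment scores tracked the orienting ratio weakly in some libraries and chromosomes, and scores after iterative correction (60 rounds) were computed beside them. Interchromosomal contacts were summed per pair of 1 Mb regions, with an expected number of at least 3, a limit set after a first output was seen.

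CTCF peaks were shared when they overlapped by at least 1 bp. Domain groupings and border counts were set against 1000 circular shifts of the borders. Alternatives covered scaling (edgeR's trimmed mean of M values and DESeq2 size factors), read minimums, added priors, fold limits, peak overlap and height, insulation squares, iterative correction and leaving out an enzyme. Simulated libraries held no changes other than 200 planted ones. For RNA these were planted only in genes with at least 200 reads, above the minimum of the rule. Among them the RNA rule recovered 31.0% to 39.5% of 2-fold and at least 99.0% of 3-fold changes, with 0 other genes. It recovered 0% to 0.5% of 1.5-fold changes. ChIP-seq libraries were simulated only over bins with at least 300 reads, and the fold limit was applied without the interval. It recovered 0% of 1.25-fold, 40.5% to 46.0% of 1.5-fold and 100% of 2-fold changes. Recovery in genes and bins with fewer reads that the rules also admit was not measured. On simulated insulation scores limma recovered 0% of changes of 0.25 log2 with 0 false calls, and 62.5% of changes of 0.5 log2 and 99.5% of changes of 1 log2 with 9 false calls in either run. Without planted changes it made 0 calls. The simulated scores took their values and noise (SD 0.1245 log2) from maps after iterative correction, with equal noise in every bin. They therefore do not give the recovery or false calls of the main test, which used the uncorrected maps.

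The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, bedtools 2.31.1, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

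Total reads of the RNA and H3K27me3 libraries stand with their results. Hi-C libraries held 27955688 and 25681097 contacts with HindIII at 0 and 60 min, and 23455935 and 37213665 with NcoI. ChIP-seq libraries at 0 and 30 min held 146044735 and 145305602 reads for H3K36me2, 137810982 and 129554661 for H3K14ac, and 148312436 and 146986880 for H1.2. Per the file headers, the CTCF libraries held 91566890 tags at 0 min and 79526496 at 60 min, with 8.17% and 9.49% of them in peaks.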

Results

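Chromatin contacts, chromatin marks and RNA were measured in T47D-MTVL breast cancer cells before and after hormone. Hi-C libraries were made with HindIII and with NcoI at 0 and 60 min of the progestin R5020 (2 libraries per time, 1 per enzyme). The RNA groups (untreated, progestin 60 min, progestin 360 min, oestradiol 360 min) and the ChIP-seq groups (H3K36me2, H3K14ac, H3K27me3 and H1.2 at 0 and 30 min, CTCF at 0 and 60 min) held 1 library each. RNA and ChIP-seq differences were therefore not checked against replicates, and "higher" and "lower" describe those libraries. The series title names the coordination of hormone-regulated genes by chromatin domains as the subject.

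The RNA libraries held 60647119 (untreated), 81449975 (progestin 60 min), 70796581 (progestin 360 min) and 68456880 (oestradiol) reads, with at least 1 read in 24055, 24847, 24394 and 24778 genes. The 10 most abundant genes took 28.2%, 29.4%, 27.1% and 25.4% of the reads. They included small structural RNAs, and the top gene was the small nucleolar RNA gene SNORD3C (5.21% and 5.00%) in the first pair and the 7SK RNA (4.78% and 4.11%) in the second. Between 23.04% and 23.47% of detected genes had fractional counts, and these held 12.1% to 12.7% of the reads.

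After 60 min of progestin, among genes with whole counts, the zinc finger factor gene KLF4 was 4.07-fold higher (15.6 against 3.83 CPM, 95% counting interval of the log2 ratio 1.74 to 2.32) and KLF6 3.59-fold higher. NET1, a guanine nucleotide exchange factor gene, was 4.34-fold higher, and PDK4, a kinase that inhibits pyruvate dehydrogenase, was 3.59-fold higher. KDM6B, an H3K27 demethylase gene, was 4.19-fold lower, the AP-1 factor gene JUNB was 3.41-fold lower, and CISH, a feedback inhibitor of cytokine signalling, was 2.98-fold lower.

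SYBU (5.44-fold), FLRT3 (4.55-fold), RASGEF1B (4.01-fold) and NEDD9 (3.23-fold) were also among the 10 highest whole-count genes. HCFC1, a transcriptional co-regulator, was 3.20-fold lower, the lipoprotein receptor gene LRP1 was 2.99-fold lower, and MED12, a subunit of the Mediator kinase module, was 2.66-fold lower. C22orf46P (3.06-fold), BCL3 (2.61-fold) and SCAF4 (2.54-fold) were lower too. The ranking over all genes fixed in advance held only genes with fractional counts, whose values are uncertain. Its top genes were ENSG00000260170, with 0 reads in untreated cells and at least 323-fold higher, ENSG00000265500 (201-fold higher) and OGFOD2 (72.0-fold higher). ZRSR2P1 (at least 124-fold lower), TRIL (22.4-fold lower) and NPIPB13 (21.8-fold lower) were at the opposite end.

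At 60 min, 5 of 20 measured progestin and glucocorticoid receptor targets were at least 2-fold higher, 0 were lower and 15 lay within the rule. SGK1, a kinase gene of steroid response with fractional counts, had a log2 ratio of 2.65, followed by KLF4 (1.89), ERRFI1 (1.54), CEBPD (1.53) and F3 (1.34). EGFR (-0.37) and CEBPB (-0.14) were the lowest members. The list median of 0.44 lay above all 10000 random lists, and it was 0.30 over members with whole counts. FKBP5 (0.33) lay within the rule at this time.
Of 22 immediate early genes, MYC (1.46) and ATF3 (1.06) were higher, JUNB (-1.66) and IER2 (-1.17) were lower, and 18 lay within the rule. None of the 22 G1/S and DNA replication genes passed, although the median of 0.13 lay at percentile 98.95 (random range -0.12 to 0.11). The cyclin D1 gene CCND1, at 1.92-fold, was its highest member. The interferon response list had a median of 0.30 (percentile 99.97) with 0 of 13 genes past the rule, and IFIT1 (0.63) and OAS1 (0.52) were highest. Among 11 luminal epithelium genes, GATA3, which encodes a luminal transcription factor, was lower (-1.23) and 10 lay within the rule (median -0.13, percentile 1.29). RARA (-1.09) was the 1 oestrogen receptor target of 16 past the rule. PGR, the progesterone receptor gene, had 166 against 261 CPM and ESR1, the oestrogen receptor gene, 75.4 against 92.4 CPM.
The remaining lists had medians within the random range. FASN (-1.03), of fatty acid synthesis, was the 1 member past the rule in sterol and fatty acid synthesis (median -0.02). None passed in G2/M and mitosis (0.02), ribosome biogenesis (-0.09), metallothioneins (-0.11), glycolysis (0.09), the basal, mesenchymal, blood and vessel markers (-0.11), architectural proteins and linker histones (0.01), polycomb and SWI/SNF (-0.06) and housekeeping genes (0.11).

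Over all genes at 60 min, 286 of 16965 were at least 2-fold higher and 283 lower. Among whole-count genes the numbers were 56 and 58 of 12620 (0.903%), and among genes with fractional counts 10.5% passed the rule.

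**Figure D1:**
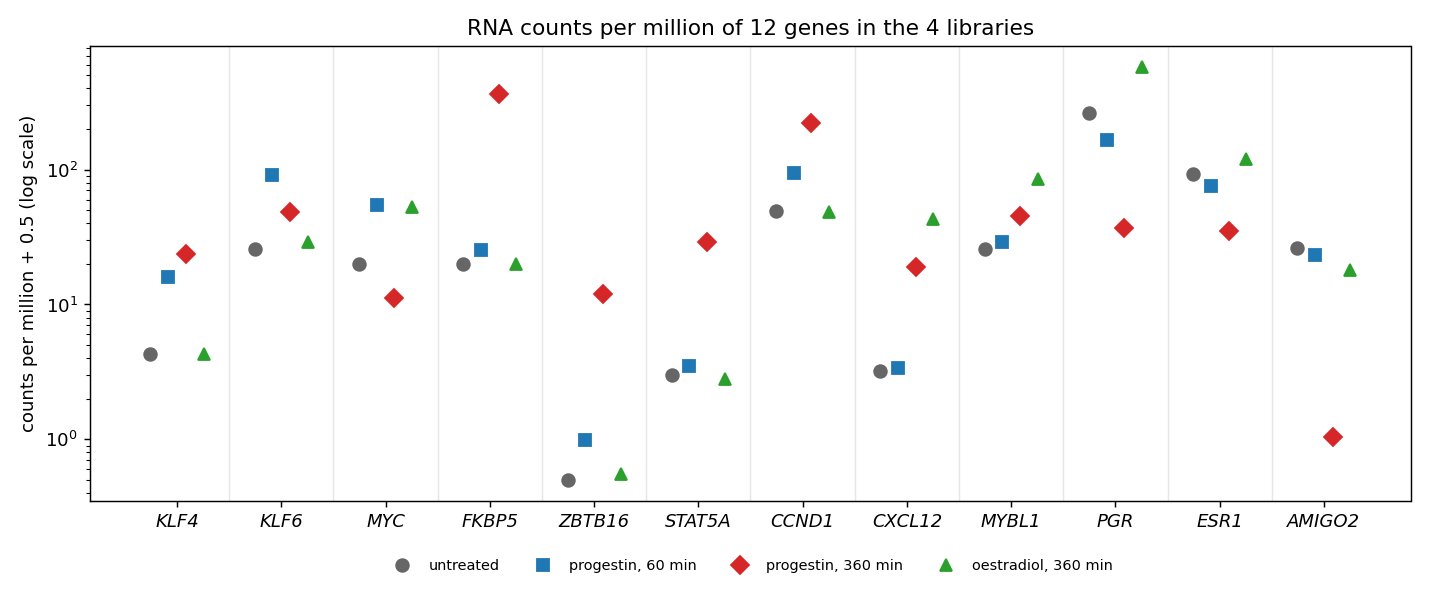
RNA levels of 12 genes in the 4 RNA libraries, as CPM plus 0.5 on a log axis, with 1 point per library. FKBP5 had 361 CPM after 360 min of progestin against 19.6 CPM in untreated cells, and PGR had 36.4 CPM after progestin and 579 CPM after oestradiol at 360 min.

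After 360 min of progestin, classic steroid receptor target genes were among the whole-count genes with the highest ratios to untreated cells. FKBP5, which encodes an immunophilin co-chaperone of steroid receptors, had 361 against 19.6 CPM (18.5-fold, 95% counting interval of the log2 ratio 4.09 to 4.33). ZBTB16, a zinc finger transcription factor gene, had 11.6 CPM against 0 reads, which made it at least 117-fold higher. F3, the tissue factor gene, was 19.5-fold higher and KLF15, a Krüppel-like factor gene, 31.1-fold higher. The progesterone receptor gene PGR was 7.18-fold lower (36.4 against 261 CPM, log2 interval -2.93 to -2.76). The adhesion protein gene AMIGO2 was 48.1-fold lower, the growth factor gene TGFB2 11.8-fold lower and CISH 11.6-fold lower.

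ACOT6 (38.8-fold), TRIM22 (38.8-fold), OTULINL (22.1-fold) and CORO2B (0 reads in untreated cells, at least 94.8-fold) were also among the 10 highest whole-count genes. TNFSF15 (9.36-fold), LMCD1 (8.41-fold), SHROOM2 (7.99-fold), HEG1 (6.12-fold) and the long noncoding RNA DSCAM-AS1 (6.12-fold) were among the lowest. The ranking over all genes also held SGK1, 69.3-fold higher with fractional counts, and the readthrough gene P2RX5-TAX1BP3, at least 251-fold higher. VPS51 (22.5-fold) and C2orf74 (14.5-fold) were at its lower end. P2RX5-TAX1BP3, VPS51 and C2orf74 had fractional counts too.

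At 360 min, 12 of 21 progestin and glucocorticoid receptor targets were higher, 0 lower and 9 within the rule (median 1.39, above all random lists). Besides FKBP5, ZBTB16, SGK1 and F3, these included STAT5A, a prolactin signalling factor (3.26), KLF4 (2.44), CEBPD (2.31), the phosphatase gene DUSP1 (1.88) and EGFR (1.52). IRS2 (-0.55) and ELF5 (-0.43) were the lowest members. Of 22 G1/S and DNA replication genes, 6 were higher and 0 lower (median 0.68, above all random lists). GINS2, a replicative helicase subunit (2.39), CCND1 (2.17), the cyclin E2 gene CCNE2 (1.51), E2F1 (1.44), ORC1 (1.42) and CDC6 (1.06) were these. None of 15 G2/M and mitosis genes passed (median -0.20, percentile 4.22). In glycolysis, the hexokinase gene HK2 (1.61) and the glucose transporter gene SLC2A1 (1.60) were higher and 8 lay within the rule (median 0.31, percentile 98.7). In sterol and fatty acid synthesis, SCD, a fatty acid desaturase with fractional counts, was higher (1.01) and 11 lay within the rule (median 0.42, percentile 99.92).
The luminal epithelium list was lower than all 10000 random lists (median -0.90), with 4 of 11 genes lower and 0 higher. GATA3 (-1.43), ESR1 (-1.40), the keratin gene KRT18 (-1.38) and FOXA1 (-1.02) were these. Of 16 oestrogen receptor targets, the chemokine gene CXCL12 (2.57), GREB1 (1.43, fractional counts) and RET (1.28) were higher, while PGR (-2.83), RARA (-1.82) and CELSR2 (-1.20) were lower (median -0.36, percentile 0.43). Of 21 immediate early genes, 5 were lower and 0 higher (median -0.11, percentile 22.4). They were the MAP kinase feedback genes DUSP6 (-1.77), DUSP5 (-1.53), DUSP4 (-1.35) and SPRY2 (-1.43), and CTGF (-1.60).
In the interferon response list IFIT1 (-1.28) and IRF9 (-1.25, fractional counts) were lower and 11 lay within the rule (median -0.32). NCL (-1.02) was the 1 ribosome biogenesis gene past the rule (median 0.17), CD44 (2.52, fractional counts) and TP63 (-1.25) passed among the basal, mesenchymal, blood and vessel markers (median -0.31 over 6 genes), and no member of the other lists did. Their medians were 0.13 for metallothioneins (3 genes), -0.14 for polycomb and SWI/SNF, 0.01 for housekeeping genes and -0.01 for architectural proteins and linker histones. The last was 0.03 under either other scaling.

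Over all genes at 360 min, 879 of 16817 were at least 2-fold higher and 892 lower, and among whole-count genes 528 and 502 of 12527. Of the whole-count genes past the rule at 60 min, 39 higher and 41 lower ones passed it in the same direction at 360 min. Independent lists would share about 2.40 and 2.37. These expected numbers are approximate, since they use the 12303 whole-count genes with at least 50 reads in both 360 min comparisons with untreated cells. The lists themselves were not limited to those genes. Both comparisons share the untreated library. In 100 simulated draws of unchanged libraries no gene was shared, but at most 1 gene passed the rule at 60 min and 2 at 360 min. The draws hold counting error only, so they do not show how much of the overlap came from the shared untreated library.

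After 360 min of oestradiol, known oestrogen receptor targets were among the whole-count genes with the highest ratios to untreated cells. CXCL12, a chemokine gene, was 15.6-fold higher (42.2 against 2.70 CPM, 95% counting interval of the log2 ratio 3.64 to 4.30). The transcription factor genes MYB and MYBL1 were 5.06-fold and 3.32-fold higher. PGR had 579 against 261 CPM (2.22-fold) and ESR1 120 against 92.4 CPM (1.30-fold). RNF144B, an E3 ubiquitin ligase gene, was 3.40-fold lower and the potassium channel gene KCNC1 3.59-fold lower.

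NKAIN1 (10.0-fold), SUSD3 (6.39-fold), FGD3 (5.46-fold), OLFM1 (4.07-fold) and the complement receptor gene C5AR2 (3.47-fold) were higher, as were the pseudogenes HSPA8P7 (4.33-fold) and HSPA8P5 (3.62-fold). PALMD (3.10-fold), RTL5 (2.89-fold), the deubiquitinase gene USP2 (2.88-fold), TNS4 (2.76-fold), ARHGAP15 (2.43-fold), SPRY1 (2.40-fold), LRP1 (2.22-fold) and SOX9 (2.21-fold) were lower. In the ranking over all genes, which held only genes with fractional counts, DCST1 (129-fold) and OGFOD2 (45.4-fold) were higher, and NPIPB13 (32.9-fold) and ACAD11 (28.6-fold) lower.

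With oestradiol, 7 of 16 oestrogen receptor targets were higher, 0 lower and 9 within the rule (median 0.73, above all random lists). Besides CXCL12, MYB, MYBL1 and PGR, these were GREB1 (2.69, fractional counts), the carbonic anhydrase gene CA12 (2.30-fold) and SIAH2 (2.20-fold). CELSR2 (-0.34) was the lowest member. The median of ribosome biogenesis genes was 0.53, also above all random lists, with 0 of 14 genes past the rule and POLR1B, an RNA polymerase I subunit (0.87), highest. Glycolysis had a median of 0.34 (percentile 99.94) with HK2 (0.80) highest and 0 of 10 genes past the rule. MYC (1.39) was higher and CTGF (-1.72) lower among 21 immediate early genes (median -0.21, percentile 0.12). No gene of G2/M and mitosis (median -0.16, percentile 0.33) or of architectural proteins and linker histones (median -0.11, percentile 1.33) passed.
None of 20 progestin and glucocorticoid receptor targets passed (median -0.06), and FKBP5 had 19.4 against 19.6 CPM. No gene of the other 8 lists passed. Medians were 0.16 for G1/S and DNA replication, 0.17 for sterol and fatty acid synthesis, -0.35 for metallothioneins, -0.04 for interferon response, 0.16 for the basal, mesenchymal, blood and vessel markers and -0.04 for polycomb and SWI/SNF. The luminal epithelium median of 0.02 was -0.07 and the housekeeping median of 0.08 was -0.01 under DESeq2 size factors.

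Over all genes, 412 of 16889 were at least 2-fold higher and 232 lower with oestradiol, so 64.0% of the genes past the rule were higher. Among whole-count genes 117 of 12564 were higher and 36 lower (76.5% higher). The median of all genes was 0.07, and under DESeq2 size factors it was -0.02, with 354 genes higher and 270 lower (56.7% higher).

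At 360 min, progestin and oestradiol were compared with each other without the shared control. The median of all genes was -0.12 by total counts and -0.004 under DESeq2 size factors, so small differences depend on the scaling. PGR was 15.9-fold lower with progestin than with oestradiol (36.4 against 579 CPM), AMIGO2 32.4-fold, CISH 25.1-fold and FGD3 14.1-fold lower. F3 was 33.6-fold, KLF15 32.04-fold, TRIM22 25.5-fold and FKBP5 18.6-fold higher with progestin. ZBTB16 had 818 reads with progestin and 4 with oestradiol (198-fold, 95% counting interval of the log2 ratio 5.77 to 10.68), and CORO2B was at least 107-fold higher.

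ZBTB7C (57.7-fold), CYRIA (25.2-fold) and SLC25A18 (21.1-fold) were also higher with progestin, and SUSD3 (15.4-fold), YEATS2-AS1 (13.0-fold), TGFB2 (10.9-fold), PHACTR1 (9.02-fold), DSCAM-AS1 (8.72-fold) and PXK (7.47-fold) lower. The ranking over all genes added, with fractional counts, PCDHA14 (38.2-fold) and ACAD11 (30.3-fold) higher and TNXB (41.7-fold) and PCDHA6 (22.6-fold) lower.
The progestin and glucocorticoid receptor targets were higher with progestin (13 of 21, median 1.52) and the oestrogen receptor targets lower (8 of 16, median -1.02), beyond all random lists in either case. RARA was 5.83-fold, MYB 6.58-fold and STC2, a secreted glycoprotein gene, 3.25-fold lower. In G1/S and DNA replication, 4 of 22 genes were higher, GINS2 (4.85-fold), CCND1 (4.64-fold), CCNE2 (1.53) and E2F1 (1.04), and the median of 0.42 lay above all random lists. In luminal epithelium ESR1 (-1.78) and KRT18 (-1.40) were lower (median -0.67, below all random lists). The 5 lower immediate early genes were MYC (-2.24), DUSP6 (-1.27), SPRY2 (-1.18), DUSP5 (-1.02) and FOS (-1.01), and the median was -0.25. Ribosome biogenesis had a median of -0.36 (percentile 0.25) and sterol and fatty acid synthesis of 0.25 (percentile 99.7), with no gene past the rule in either list. The 2 lower interferon response genes were IFIT1 (3.66-fold) and, with fractional counts, IRF9 (-1.04), and the median was -0.39. SLC2A1 (1.16) in glycolysis and CD44 (3.09-fold) among the basal, mesenchymal, blood and vessel markers (median -0.22) were the 1 gene past the rule in their lists. Polycomb and SWI/SNF had a median of -0.15.
No metallothionein (median 0.51), G2/M and mitosis, architectural or housekeeping gene passed. The medians of G2/M and mitosis (-0.07) and glycolysis (-0.09) were 0.06 and 0.04 under DESeq2 size factors, and those of the architectural and housekeeping lists, 0.02 each, were 0.15 each.

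Over all genes, 722 of 17044 were at least 2-fold higher with progestin and 677 lower (51.6% higher), against 860 and 540 (61.4% higher) under DESeq2 size factors. Among whole-count genes the numbers were 434 and 321 of 12690. The log2 ratios of both hormones to untreated cells correlated across 17910 genes (Pearson r 0.449, Spearman correlation 0.498), and genes are not independent replicates. Counting error with the shared untreated library alone gave an r of 0.535 in simulated unchanged libraries, but a covariance of 0.0120 against 0.144 observed. With whole counts only the observed covariance was 0.0828. The simulation leaves out spread between libraries beyond counting error, so it does not bound what the shared library can give. Among whole-count genes, 25 were higher (3.90 for independent lists) and 18 lower (1.47) with both hormones. In 100 simulated draws of unchanged libraries no gene was shared, and these leave out real effects, so neither number shows how much of the overlap came from the shared untreated library.

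**Figure D2:**
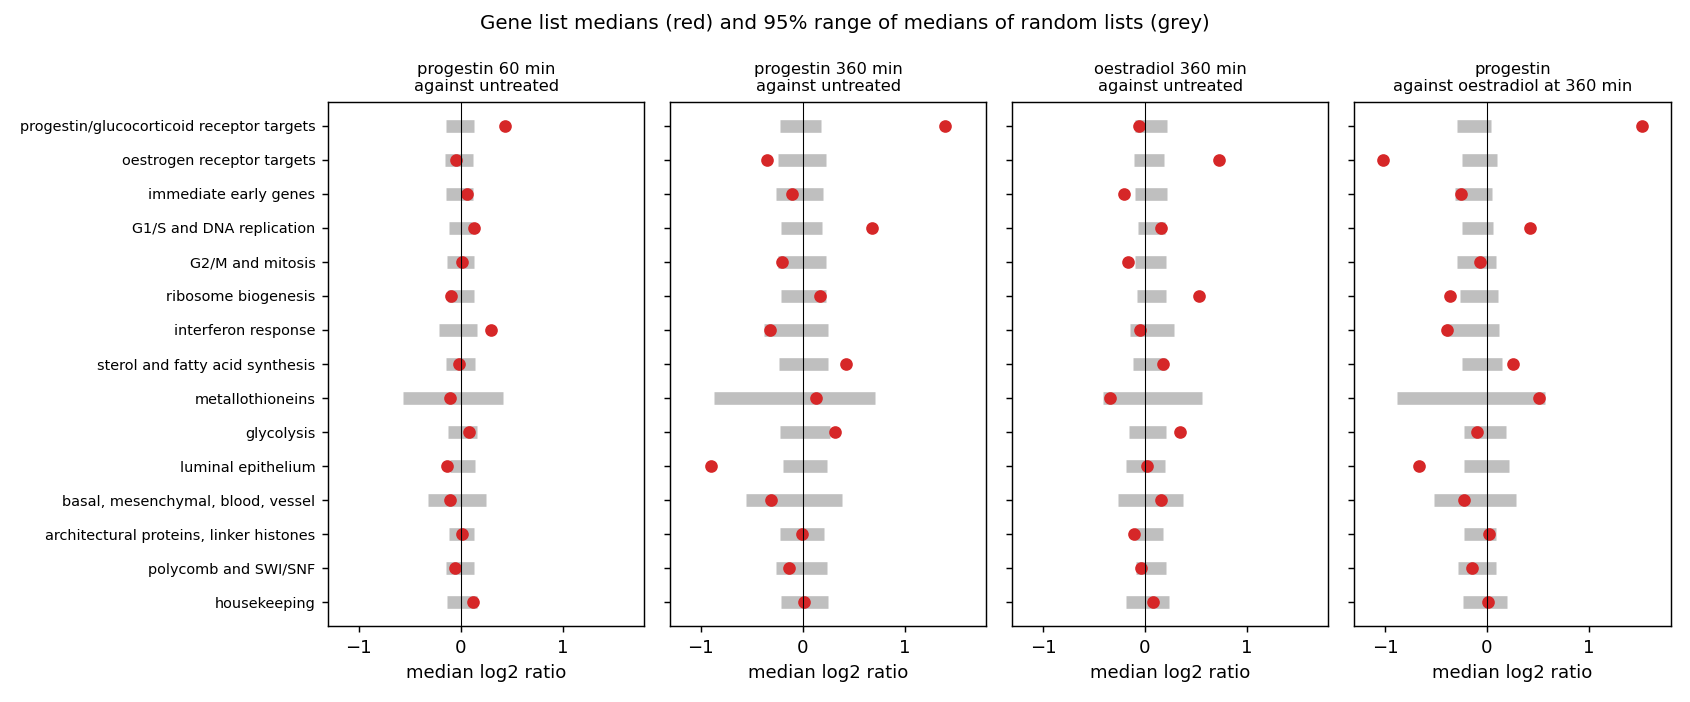
Median log2 ratio of each of the 15 gene lists (points) in the 4 RNA comparisons, with the 95% range of medians of 10000 random lists matched on expression (grey bars). The progestin and glucocorticoid receptor targets had a median of 1.39 after 360 min of progestin, and the oestrogen receptor targets 0.73 after oestradiol.

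RNA ratios of neighbouring genes were weakly correlated. Across adjacent, non-overlapping protein-coding genes with whole counts (8835 to 8913 pairs), the log2 ratios correlated with an r of 0.053 at 60 min and 0.126 at 360 min of progestin, 0.103 with oestradiol and 0.149 for progestin against oestradiol. None of 1000 shuffles of the ratios over genes gave as high a value in any of the 4. Genes 5 places apart had an r of 0.006, 0.004, 0.015 and 0.002, and genes 10 places apart 0.0238 (11 of 1000 shuffles as high), 0.00675 (272), 0.0121 (111) and 0.0215 (25). With fractional counts included, the adjacent values were -0.025 at 60 min, 0.0867 at 360 min, 0.0270 with oestradiol and 0.110 for progestin against oestradiol.

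After 30 min of progestin, the marks differed little between libraries at 100 kb. H3K14ac, an acetylation of histone H3, had the lowest ratios in chromosome 9 at 12700001 to 12800000 (2.02-fold lower, log2 -1.02, 95% counting interval -1.08 to -0.95) and 13000001 to 13100000 (-0.96), and in chromosome 14 at 38000001 to 38100000 (-0.84). Its highest ratios lay in chromosome 1 at 2600001 to 2700000 (0.74) and in chromosome 22 at 49000001 to 49100000 (0.71) and 48900001 to 49000000 (0.66). H3K14ac was higher over whole chromosomes 19 (median log2 0.18), 22 (0.16), 16 (0.14), 20 (0.11) and 17 (0.08), and lower over 4 (-0.12) and 13 (-0.10). H3K27me3, the polycomb mark, was lower over chromosomes 19 (-0.17), 22 (-0.08) and 17 (-0.07). With 1 library per time, these chromosome differences cannot be told apart from base composition read differently by the libraries.

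The bins at least 1.5-fold apart numbered 36 of 28241 for H3K14ac (14 higher, 22 lower), 5 of 28258 for H3K36me2 (0 higher, 5 lower), 2 of 28256 for H1.2 (1 higher, 1 lower) and 0 of 28530 for H3K27me3. The H3K14ac split was 26 higher and 18 lower under DESeq2 size factors, 28 and 18 when scaled by the bins of lowest signal, 6 and 19 at a minimum of 300 reads, and 774 and 311 when 25% higher or 20% lower sufficed. The 5 H3K36me2 bins were in chromosome 15 at 21800001 to 21900000 (-0.99), chromosome 16 at 33700001 to 33800000 (-0.79) and at 16500001 to 16600000 (-0.69), and chromosome 9 at 68100001 to 68200000 (-0.82) and at 43500001 to 43600000 (-0.68). The 2 H1.2 bins were in chromosome 1 at 206400001 to 206500000 (0.65) and chromosome 9 at 66300001 to 66400000 (-0.66). These 7 bins held fewer than 300 reads each and were chosen for naming after their values were seen. At a minimum of 300 reads the numbers for H3K36me2 and H1.2 were 0. Among bins with at least 300 reads, for H3K36me2 the highest ratio was in chromosome 9 at 66900001 to 67000000 (0.48) and the lowest in chromosome 15 at 22000001 to 22100000 (-0.47). For H1.2 these were in chromosome 4 at 69400001 to 69500000 (0.48) and chromosome 7 at 61600001 to 61700000 (-0.55). For H3K27me3 they were in chromosome 2 at 179400001 to 179500000 (0.38) and chromosome 18 at 2900001 to 3000000 (-0.37).
The spread of ratios over bins was 4.38 times the counting error for H3K14ac, 3.71 for H3K27me3, 1.58 for H3K36me2 and 1.47 for H1.2. H3K14ac and H3K27me3 ratios of adjacent bins correlated (r 0.740 and 0.723). The H3K27me3 libraries differed in depth (133187068 and 279401384 reads) and in the catalogue number of the antibody.

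**Figure D3:**
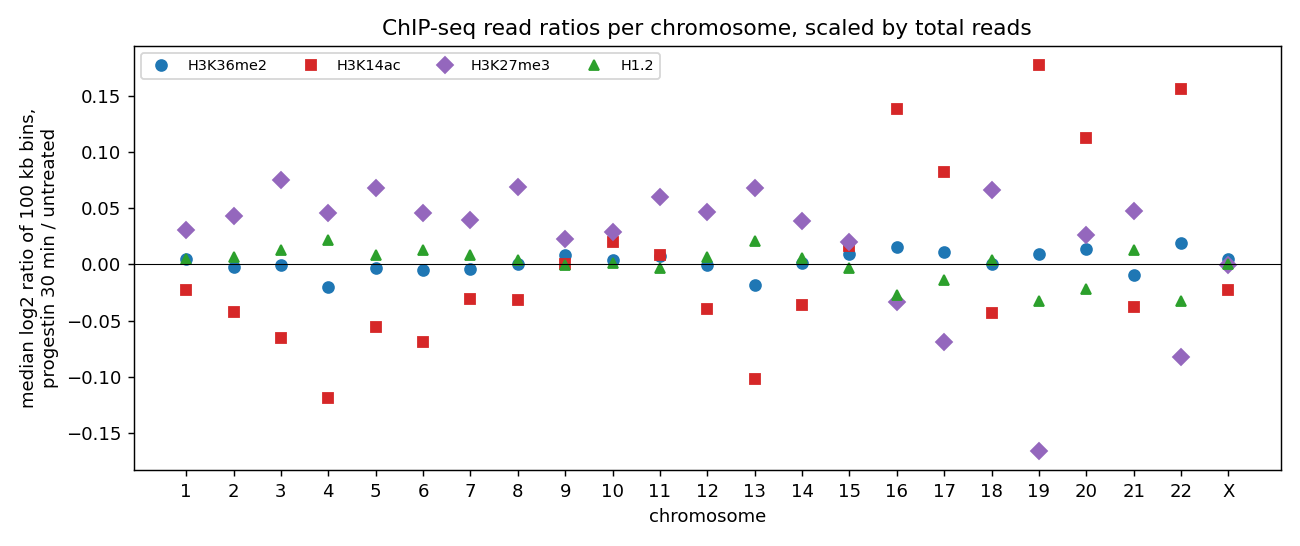
Median log2 ratio of reads per 100 kb bin at 30 min of progestin over untreated cells, per chromosome, for 4 marks with 1 library per time. H3K14ac (squares) was highest over chromosome 19 (0.18), where H3K27me3 (diamonds) was lowest (-0.17).

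Across bins, H3K14ac and H1.2 ratios went in opposite directions (Pearson r -0.588, Spearman correlation -0.602), and H3K36me2 went with H3K14ac (r 0.391) and against H1.2 (r -0.280). H3K27me3 had an r of -0.247 with H3K14ac, 0.0957 with H1.2 and -0.0869 with H3K36me2. These 6 correlations are across bins, which are not independent. H3K27me3 ratios were lower where the compartment score was higher (r -0.416), with medians of -0.01 in the A and 0.07 in the B compartment, where the median of all bins was 0.04. Of the variance of H3K14ac ratios 62.8% lay between Hi-C domains, against 60.3% to 62.2% in 95% of 1000 shifts of the borders. For H3K27me3 it was 54.2%, reached by 16 shifts. For H1.2 (36.1%) and H3K36me2 (40.8%), 162 and 733 shifts were as high. Equal windows of 9 bins, the mean domain size, which ignored the borders, held about as much or more: 62.7% for H3K14ac, 56.1% for H3K27me3, 36.7% for H1.2 and 42.4% for H3K36me2. Shifts of such windows gave medians of 62.7%, 55.8%, 36.9% and 42.3%, where shifts of the domains gave 61.2%, 53.0%, 35.6% and 41.2%.

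CTCF, the zinc finger protein found at domain borders, had 43797 peaks in untreated cells and 42975 after 60 min. Of the untreated peaks 40699 (92.9%, Wilson 95% interval 92.7% to 93.2%) overlapped a peak at 60 min, which is 94.7% of the later list. When untreated peaks were ranked by height into 4 equal parts, 76.0% were shared in the lowest part and 96.8%, 99.5% and 99.4% in the higher ones. Peaks seen at 1 time only were low, with a median height (tags scaled by the authors to the library) of 4.2 against 14.9 for shared untreated peaks. The strongest peak seen only in untreated cells lay in chromosome 10 at 42392634 to 42392826 (height 1004.2, 4.11-fold over input), with another at 42400363 to 42400555 (777.6, 4.13-fold). The strongest seen only at 60 min lay in chromosome 5 at 142093012 to 142093240 (height 86.6, 29.1-fold over input).
CTCF peaks gathered at domain borders. The 2694 border bins held 2.52 peaks each in untreated cells against 1.53 per bin overall (1.65 times), while 95% of shifted borders gave 0.961 to 1.03 times. At 60 min the ratio was 1.64 times, and 90.7% of border bins held a peak in untreated cells against 68.9% of all bins.

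**Figure D4:**
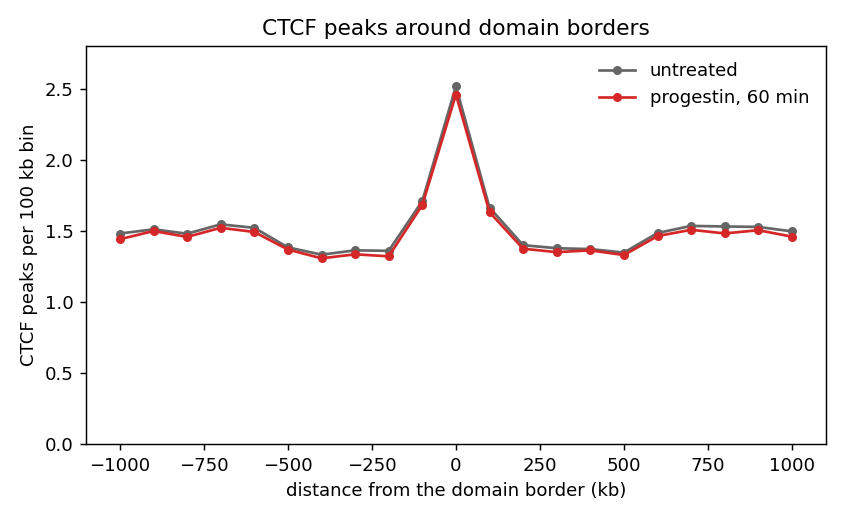
CTCF peaks per 100 kb bin by distance from the domain border, in kb, before and after 60 min of progestin. The border bins held 2.52 peaks in untreated cells and 2.46 at 60 min.

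Hi-C asked whether the contact maps differed after 60 min of progestin. The domains with the largest change of 1 sign in both enzymes lay in chromosome 19 at 43200001 to 43800000, chromosome 17 at 20300001 to 20800000 and chromosome 4 at 157000001 to 157300000, and their internal contacts fell by log2 1.34, 1.22 and 0.74. These were the 3 of 2648 domains past an adjusted p of 0.05 in limma (1.03e-14, 4.45e-12 and 0.00146), all lower in both enzymes, and 118 had an unadjusted p under 0.05. They held few contacts, against a median of 463 per domain with HindIII at 0 min: 19 and 6 with HindIII and 31 and 26 with NcoI at 0 and 60 min in the chromosome 19 domain, 10 and 3 and 17 and 18 in the chromosome 17 domain, and 70 and 41 and 37 and 31 in the chromosome 4 domain. Each value is observed contacts over those expected at the same distances on the chromosome in that library. The contacts of the chromosome 17 domain with NcoI thus did not fall in number, and its lower value there came from a higher expected number. A higher expected number also made up most of the NcoI change of log2 -1.23 in the chromosome 19 domain. The spread was pooled over all domains (SE 0.154 for each), so these p-values do not measure the spread of the single domain. With HindIII the SD of changes was 0.231 in the third of domains with the fewest contacts and 0.0925 in that with the most. With NcoI it was 0.248 and 0.244. The pooled SE leaves out the wider HindIII spread, so p-values of domains with few contacts can be far too small. After iterative correction the mean changes were -0.66 (SE 0.237), -0.72 (0.321) and -0.53 (0.0395), with -0.22, -0.13 and -0.53 in NcoI, the spread was pooled less, and limma called 0 domains (156 at an unadjusted p under 0.05); with each domain's internal share of cis contacts it called 0 (146). The domains in chromosome 3 at 49200001 to 49700000 (log2 0.56, adjusted p 0.195) and chromosome 2 at 238700001 to 239100000 (0.54, adjusted p 0.201) did not pass.

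Insulation changed in 13 of 27096 bins in limma, with 11 higher and 2 lower and with 1234 bins at an unadjusted p under 0.05. The largest changes were ranked only among bins with the same sign in both enzymes. They were in chromosome 11 at 3600001 to 3700000 (mean log2 1.22, adjusted p 0.00949) and 49100001 to 49200000 (-1.10, adjusted p 0.00949). Next came chromosome 19 at 500001 to 600000 (1.06, adjusted p 0.0120), chromosome 11 at 500001 to 600000 (1.05, adjusted p 0.00938) and chromosome X at 153900001 to 154000000 (1.01, adjusted p 0.0216). With iterative correction limma called 0 bins (1371 at an unadjusted p under 0.05), and with a 1 Mb square 0 (908). The mean changes of these 5 bins after iterative correction were 1.15 (SE 0.307, before it 0.202), -0.92 (0.1003, before 0.178), 0.91 (0.323, before 0.181), 0.82 (0.245, before 0.162) and 0.69 (0.208, before 0.179), with adjusted p from 0.105 to 0.927. The spread was then pooled less over bins (prior degrees of freedom 8.84, before 29.6), and in NcoI the 4 higher bins changed by 0.24, -0.05, 0.12 and 0.12. Across bins, uncorrected insulation changes in NcoI went with changes in coverage, a bin's share of all contacts (r 0.651). This r was 0.0169 after iterative correction, and with HindIII it was 0.0222 before and 0.00148 after. Uncorrected insulation changes in NcoI therefore cannot be told apart from coverage changes. Without the enzyme block limma called 0 insulation bins (13 at an unadjusted p under 0.05), 0 compartment bins (303) and 0 domains (2). The compartment score changed in 0 of 27761 bins in limma (828 at an unadjusted p under 0.05), and in 0 after iterative correction (1401). In some chromosomes the uncorrected score barely tracked the orienting ratio. With NcoI its absolute r was 0.526 at 0 min and 0.0108 at 60 min in chromosome 11, and 0.519 and 0.0299 in chromosome 12. After correction these were 0.604, 0.613, 0.610 and 0.619. The uncorrected score therefore cannot show whether compartments changed there.
The changes of the enzymes did not go together across the genome, with an r of -0.0429 for insulation, -0.00266 for the compartment score and 0.00378 for contacts inside domains. Insulation itself correlated at 0.952 and 0.944 between times within an enzyme and at 0.644 to 0.789 between enzymes. The uncorrected compartment score correlated less, at 0.810 with HindIII and 0.608 with NcoI between times and at 0.388 to 0.544 between enzymes. After iterative correction the compartment changes of the enzymes had an r of 0.00880.
The share of contacts within chromosomes was 40.2% at 0 and 40.2% at 60 min with HindIII, and 49.8% and 48.2% with NcoI, a mean difference of -0.830 points ± 1.15 (SD, n = 2 enzymes). The share of these under 2 Mb went from 58.5% to 56.8% with HindIII and from 56.1% to 56.9% with NcoI. The mean difference of -0.450 points was smaller than its spread (SD 1.799), and it was 0.334 points (SD 0.0892) when contacts within a bin were left out. Domains numbered 2650, with a median length of 0.8 Mb (quartiles 0.6 and 1.2 Mb). Of the borders of the untreated HindIII map 76.4% lay within 1 bin of a border at 60 min, and 82.6% with NcoI.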

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

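The tests of low counts and of a progestin response for the fractional-count genes, the test of a progestin response for H3K14ac and H1.2, and the value of 0.565 below, were chosen only after the results were seen.

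At 360 min, 10 genes with whole counts passed the 2-fold rule against untreated cells in opposite directions with progestin and with oestradiol. The difference was not tested, since each condition had 1 library. Lower with progestin and higher with oestradiol were CISH (log2 ratio of progestin to oestradiol -4.03), PGR (-3.98), FGD3 (-3.55), YEATS2-AS1 (-2.91), PXK (-2.83), MAP6D1 (-2.65), CYP2T1P (-2.52), KCTD6 (-2.22) and ARMT1 (-2.19). RPS6KA5, a nuclear kinase gene, was higher with progestin and lower with oestradiol (2.64).

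The share of cis contacts under 2 Mb moved in opposite directions with the enzymes, by -1.72 points with HindIII and 0.822 points with NcoI between 0 and 60 min, and this difference was not tested. It rested on contacts within a bin: without them the share went up with both, by 0.397 and 0.271 points.

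Interchromosomal contacts, which no comparison used, held pairs of 1 Mb regions far above the number expected from coverage in all 4 libraries. The lowest fold over the libraries was 48.3 for chromosome 9 at 16000001 to 17000000 with chromosome 15 at 27000001 to 28000000, 40.5 for chromosome 8 at 37000001 to 38000000 with chromosome 14 at 25000001 to 26000000, and 30.5 for chromosome 10 at 58000001 to 59000000 with chromosome 20 at 54000001 to 55000000. It was 28.9 for chromosome 3 at 169000001 to 170000000 with chromosome 10 at 81000001 to 82000000, and 24.0 for chromosome 1 at 147000001 to 148000000 with chromosome 16 at 71000001 to 72000000.

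At 60 min of progestin, genes with fractional counts passed the 2-fold rule far more often than whole-count genes. Low counts are argued against as the whole cause, since with at least 200 reads the share was still 10.5 times as high (9.32% against 0.889%), although with at least 1000 reads it was 7.76 times as high (5.48% against 0.707%) and the excess 4.77 points. A progestin response is argued against too: the share at 60 min was 0.606 of that at 360 min, against 0.110 for whole-count genes, and oestradiol against untreated cells showed an excess of 10.1 points beside 9.57 at 60 min of progestin. A candidate explanation is that reads were divided between overlapping genes in different proportions in each library: in 906 overlapping pairs the log2 ratios correlated at -0.142 (95% interval -0.21 to -0.08), against 0.0934 (0.0351 to 0.151) in 1122 overlapping pairs with whole counts. The summed reads of the pairs with fractional counts passed the rule in 4.97% of pairs, against 10.8% of their members. Sums passed less often with whole counts too (0.446% against 0.802%), so the drop on summing does not decide. Summing undoes a division between the genes of a pair, yet sums with fractional counts still passed more often (4.97% against 0.446%). This argues against such division as the whole cause in these pairs, and it can be a part. Division with genes outside the pair was not tested. Reads shared between near-identical copies stay open, since they were not tested.

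H3K14ac and H1.2 ratios at 30 min went in opposite directions across bins (r -0.624 over the bins of the Hi-C maps). The untreated NcoI to HindIII coverage ratio, taken as a stand-in for base composition, went with both (r 0.518 for H3K14ac and -0.385 for H1.2), and the partial correlation given it was -0.538, 0.862 of the plain value (0.843 to 0.879 over 1000 resamples of chromosomes), or -0.474 with the NcoI coverage change added. The bound of 0.8 set beforehand does not exclude base composition, since a stand-in that correlates with it at 0.565 would leave this remainder with base composition as the whole cause. A response to progestin, base composition and a difference between the single libraries of each time cannot be told apart: H3K14ac ratios followed the 60 min coverage change with NcoI (r 0.623) and went against it with HindIII (r -0.305). With 1 library per time the design keeps this open.

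In the HindIII libraries, bins on different chromosomes met exactly 2 times 3.47 (0 min) and 5.47 (60 min) times as often as chance gives, against 1.18 and 1.12 with NcoI. Rearranged chromosomes are argued against, since the 1% of 1 Mb pairs with the most contacts held 7.09% and 5.61% of the HindIII excess. Pairs counted more than once are a candidate explanation, since in the 25% of chromosome pairs with the fewest contacts the ratio was 6.61 at 0 min and 11.1 at 60 min. Beyond rearranged chromosomes, no biological explanation was tested for this pattern.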

How the results depend on the processing

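The alternatives with whole counts only, with intervals on reads, over the bins kept in the Hi-C maps, all those for neighbouring genes, and the spread of domain changes by contacts were chosen after seeing the data. Of 240 alternatives for the 60 list medians, 236 moved the value by less than the spread of its random lists and 13 changed its sign, none of them for a median outside the 95% range of its random lists. Of 640 for 160 named gene results, 637 left the gene on its side of 2-fold and 0 changed its sign. These 640 alternatives varied only the scaling and the added prior, and most of the genes were picked as extremes. They do not test the fractional counts. Where a value differs, the cause was not tested unless the alternative's own construction gives it, such as fewer genes or bins.

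The 2-fold counts at progestin 60 min, progestin 360 min, oestradiol and progestin against oestradiol were 285, 1079, 334 and 827 with a prior of 2 CPM, 1661, 4265, 1955 and 3562 at 1.5-fold, and 114, 1030, 153 and 755 with whole counts only. The correlation between hormones was 0.429 with whole counts only, and the neighbour correlations were -0.025, 0.0867, 0.0270 and 0.110 with fractional counts included.

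ChIP-seq bins numbered 0 for H3K36me2 and 0 for H1.2 at 300 reads, 11 and 10 without a minimum, and 21, 1085, 10 and 15 for H3K36me2, H3K14ac, H3K27me3 and H1.2 when 25% higher or 20% lower sufficed. The correlation of H3K14ac with H1.2 was -0.602 by Spearman, -0.624 over bins of the Hi-C maps, -0.608 at 300 reads and -0.601 on autosomes. Shared CTCF peaks were 93.4% with centres within 1 kb, 93.6% for the stronger part of each list and 91.3% for the strongest 10000. The border ratio was 1.83 with stronger peaks and 1.56 with borders from a 300 kb square.

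Leaving out an enzyme gave -1.72 to 0.822 points for the share under 2 Mb and -1.64 to -0.0156 for the cis share, and the former was 0.334 without contacts inside a bin. Over bins above the lowest 5% of coverage the cis share changed by 0.459 points with HindIII and -1.801 with NcoI, in opposite directions. Limma called 26 insulation bins with a 300 kb square, 0 with a 1 Mb square, 0 without the enzyme block and 0 after iterative correction. It called 0 domains without the block, 0 with the internal share of cis contacts and 0 after iterative correction. Without an enzyme 1 library per time was left, with no residual degrees of freedom, so there was no limma test. The insulation changes of the enzymes correlated at 0.0129 after iterative correction. The grouping of RNA ratios by domain was not run. Domains held a median of 455 to 943 contacts per library. The SD of their changes was 0.231 in the third with the fewest contacts and 0.0925 in that with the most with HindIII, but 0.248 and 0.244 with NcoI. After iterative correction it was 0.206 and 0.0683, and 0.140 and 0.0437, so fewer contacts went with a wider spread except in the uncorrected NcoI maps.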

Other observations

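The test of NcoI and HindIII contacts against the ChIP-seq ratios below was chosen only after the results were seen.

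Genes of 1 family differed in direction after 360 min of progestin. The MAP kinase phosphatase gene DUSP1 was 3.82-fold higher, while DUSP4 was 2.67-fold and DUSP5 3.32-fold lower. The glucocorticoid-induced leucine zipper gene TSC22D3 had 58.3 CPM after progestin and 31.7 CPM in untreated cells, and 19.2 CPM after oestradiol. The period gene PER1, of the circadian clock, had 10.3 CPM after progestin, 6.38 CPM after oestradiol and 3.82 CPM in untreated cells, with fractional counts. The cyclin D1 gene CCND1 had 221 CPM after progestin and 47.6 CPM after oestradiol, against 48.6 CPM in untreated cells. GREB1, an oestrogen receptor cofactor gene with fractional counts, had 181 and 435 CPM against 66.9 CPM.

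In the NcoI maps as deposited, the change of contacts inside a domain from 0 to 60 min went with its 30 min ChIP-seq ratios. Across 2648 domains the values of r were 0.587 for H3K14ac, 0.452 for H3K36me2, -0.474 for H3K27me3 and -0.526 for H1.2. In the HindIII maps these were -0.0324, 0.0138, 0.0316 and 0.0772. After iterative correction the values with NcoI were 0.0400, 0.0418, 0.0154 and -0.0154. Coverage changes of the enzymes correlated at -0.273 across bins.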
